A study of Mus musculus with 12 samples.

How the data were processed

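RNA was sequenced from plasmacytoid dendritic cells of BALB/c mouse bone marrow in 12 libraries, 3 from each of 4 groups. The groups were cells cultured for 24 h with CpG-A, CpG-B or CpG-C oligodeoxynucleotides at 0.5 µM and control cells without an oligodeoxynucleotide. Per the labels' protocols the cells were sorted before RNA extraction with Trizol. The labels describe neither the gate of the sort nor whether it came before or after the culture. They do not say whether the replicates of a group came from separate animals, so every p-value given here measures only the spread between samples.

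A single gene table was used. Its expression values are FPKM (fragments per kilobase of transcript and per library size), rounded to 2 decimals, as deposited with 1 column per library. The submitters' processing notes name HISAT, Bowtie2 2.2.5, StringTie, GATK and RSEM 1.2.8 without giving their order or role, and the genome build mm10. The deposited table also holds the authors' log2 ratios of group means for the 6 pairs of groups. A p-value and a q-value for each pair are given per the file headers, and the test behind them is not stated there. The length of the longest transcript of each gene is given per the file headers and was used only to estimate depth. The deposited log2 ratios and q-values entered no comparison and were only set beside the calls made from the FPKM values.

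The table had 21574 lines, of which 1 was broken and left out. The remaining 21573 genes were 17590 known genes with NCBI gene numbers and 3983 genes named only by the sequencing provider. Of the known genes, 17546 (99.7%) had their number in a RefSeq gene table, 16817 had the same symbol there, and 24 symbols that a spreadsheet had turned into dates were restored from their numbers. Coordinates are those of the table, on mm10, counted from 1.

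No read counts were used, so the depth was estimated from the values: at the depth and fragment length fitted to each library, 60% to 80.5% of low FPKM values of short genes lay within 0.1 fragments of a whole number, against at most 34.9% with the lengths shuffled between genes. The estimates were 22800000 to 28400000 fragments per library. They are rough, with 95% of 100 resamplings of the genes between 22500000 and 23700000 for control replicate 1 and between 15700000 and 34800000 for CpG-B replicate 3. The shuffling and resampling were chosen after seeing the data. Counting intervals were not computed, since FPKM values carry no counts.

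FPKM values were changed to log2 after adding 1. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 11641 genes, 9948 known and 1693 provider-named. All 12 libraries were fitted together with 1 mean per group in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation along a mean-variance trend. The fit had 8 residual and 6.81 prior degrees of freedom. Adjusted p-values are those of limma's moderated test with Benjamini-Hochberg adjustment over all genes tested in a comparison, and a gene was called changed at an adjusted p below 0.05. Log2 differences are differences of group means on that scale, with the fit's standard error (SE) or 95% interval. They depend on the added 1 where a group lies near 0, and no difference is given against a group listed at 0 in all 3 libraries. An exact permutation test of 3 samples against 3 cannot go below 0.1, so single genes were not tested that way.

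The groups, comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. Named genes are, for each class against control, the 10 largest rises and 10 largest falls among called genes whose samples did not overlap between the groups and whose higher group averaged at least 5 FPKM, leaving out predicted and clone names. For each pair of classes the same rule named 5 genes in each direction. Up to 4 called members of each list with at least 1 FPKM were also named. A fixed set was followed in every comparison: Ifnb1, Ifna4, Ifna2, Irf7, Isg15, Ifit1, Cxcl10, Il6, Tnf, Il12a, Il12b, Ccl3, Ccl5, Cd40, Cd80, Cd86, Cd274, Ccr7, H2-Ab1, Ciita, Siglech, Tcf4, Tlr9, Myd88 and Bst2. Cd80 did not reach the minimum and was not tested. A gene named outside the rule is said to be so.

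The pathway lists with members that could be tested were type I and III interferons, interferon-stimulated genes, inflammatory cytokines, chemokines and their receptors, NF-kB pathway and targets, dendritic cell maturation and co-stimulation, MHC class I presentation, MHC class II presentation, plasmacytoid dendritic cell identity, TLR9 signalling, negative feedback, apoptosis and survival, cell cycle, glycolysis, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis and uptake, unfolded protein response, ribosomal proteins, and stress and dissociation. Marker lists of other cell types that a bone marrow sort could hold covered B cells and plasma cells, T cells, natural killer cells, neutrophils, monocytes and macrophages, conventional dendritic cells, erythroid cells, and progenitors. A list of mitochondrially encoded genes (0 of 26 names in the table) and one of mast cells and basophils (0 of 5 members in the table passed the minimum) could not be tested. Lists were tested with limma's camera against all other genes tested, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment within a comparison, separately for the 20 pathway lists and the 8 cell type lists. The same test with a correlation estimated from the data, and limma's fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. Some genes sit in more than 1 list, such as Cxcl10, Cd40, Relb and Irf7.

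Genes in near-identical families may share reads, so single values are uncertain for the Bcl2a1, interferon alpha, Ly6, Phf11, Klk1, Ifitm, Hamp and Lilrb4 families.

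The fit was tested on simulated data built from the gene means and fitted spread of the real libraries, with 50 genes changed at each of 4 sizes per comparison. Noise was drawn independently for each gene and library. The changed genes all had means well above the minimum, so recovery of genes near it was not tested. Depending on the comparison the fit recovered 18% to 42% of genes changed by 2 log2 units, 66% to 80% at 4 and 80% to 96% at 6. False calls numbered between 4 (among 154 for CpG-A against control and 141 for CpG-B against CpG-C) and 9 (among 158 for CpG-B against control). Of 20 simulated lists raised by 2 log2 units camera found 20, and of 20 unchanged lists it found 0. The simulated genes were not correlated with each other, so this does not show how the preset correlation performs on the real lists.

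Alternatives were 2 other pseudocounts, 0.1 and 0.01, 2 further scalings of the libraries, another filter on low values, a term for the replicate number, a fit of only the 6 samples compared, other thresholds, other list tests and leaving out each library in turn. Robust moderation, library weights, quantile normalization, a filter at 5 FPKM and leaving out the 4 libraries numbered 1 were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.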

Results

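Plasmacytoid dendritic cells sense unmethylated CpG DNA through the endosomal receptor TLR9 and are a main source of type I interferon. The series compares 3 classes of synthetic CpG oligodeoxynucleotides in these cells. CpG-A has a palindromic phosphodiester core with phosphorothioate poly-G ends, CpG-B is a fully phosphorothioate strand, and CpG-C is fully phosphorothioate with a palindrome. RNA-seq was done on bone marrow plasmacytoid dendritic cells of BALB/c mice aged 56 to 63 days after 24 h with CpG-A, CpG-B or CpG-C at 0.5 µM or without CpG (control). Each of the 4 groups had 3 libraries. The values were FPKM for 21573 genes, of which 11641 reached the minimum of 1 FPKM in 3 libraries and were tested with limma on the log2 scale after adding 1. The depth, estimated from the values, was 22800000 to 28400000 fragments per library.

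Between 11980 (CpG-A replicate 1) and 15210 (CpG-B replicate 1) genes had a value above 0, and between 7437 (CpG-A replicate 1) and 10622 (control replicate 3) reached 1 FPKM. The mean Pearson correlation of a library with the others of its group, across the tested genes, lay between 0.763 for control replicate 1 and 0.864 for CpG-B replicate 3. The first 3 principal components held 22.2%, 15.9% and 14.4% of the variance. The replicate numbered 1 had the lowest mean correlation within its group in all 4 groups. Its weight, estimated from the residuals, was 0.426 with CpG-A, 0.462 with CpG-C and 0.428 in control, against 0.866 with CpG-B and 0.867 to 2.28 in the libraries numbered 2 and 3. The median SE of a log2 difference was 0.841. In simulated data 18% to 42% of changes of 2 log2 units in genes well above the minimum were called, depending on the comparison.

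**Figure D1:**
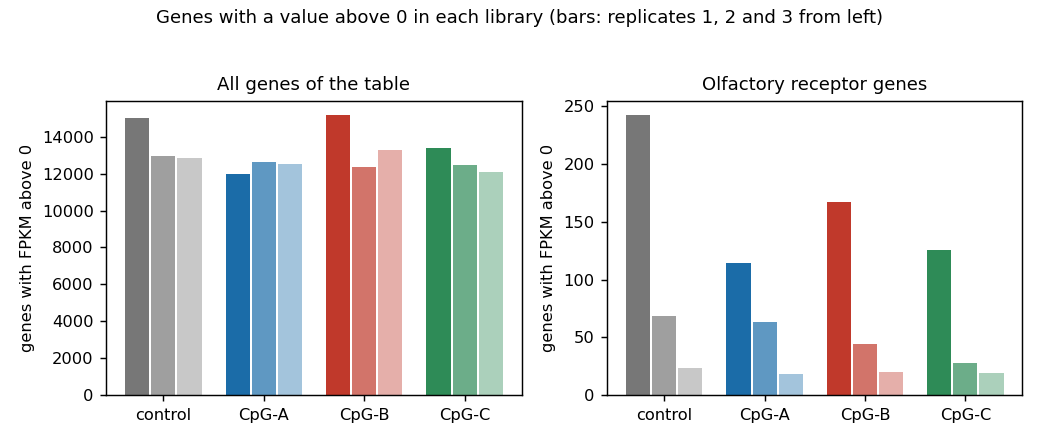
Number of genes with an FPKM above 0 in each library, for all genes (left) and olfactory receptor genes (right). The libraries numbered 1 of CpG-B and control had 15210 and 15004 genes above 0.

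The first comparison, CpG-A against control, asked which transcripts this class changed. Secretin transcripts, Sct (gene 20287, chromosome 7, 141278329 to 141279133), were the largest rise, from 25.1 ± 41.2 to 2539 ± 885 FPKM (SD, n = 3 per group; log2 difference 8.40, SE 0.963, limma adjusted p = 0.000195). Ifit3 (gene 15959, chromosome 19, 34583529 to 34588982), an antiviral interferon-induced gene, rose from 0.81 ± 0.845 to 333 ± 141 FPKM (log2 difference 7.55, SE 0.473, limma adjusted p = 1.15e-06). Cxcl10, a chemokine induced by interferon, rose from 0.223 ± 0.17 to 334 ± 130 FPKM by 8.03 log2 units (SE 0.67), and Cd40, a co-stimulatory receptor, from 0.203 ± 0.107 to 128 ± 58.5 FPKM by 6.64 (SE 0.559). Cd209a (gene 170786, chromosome 8, 3743395 to 3748984), a C-type lectin, was the largest fall, from 322 ± 143 to 1.03 ± 1.1 FPKM (log2 difference -7.35, SE 0.959, limma adjusted p = 0.000554).

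Among interferon genes, Ifna9 averaged 160 ± 175 FPKM with CpG-A and 0.03 ± 0.052 in control (log2 difference 6.52, SE 1.01, adjusted p = 0.00264). Ifna12 averaged 13 ± 9.8 FPKM and was listed at 0 in all 3 control libraries. Ifnb1 (gene 15977, chromosome 4, 88522025 to 88522794) stood at 8054, 4.55 and 229 FPKM in the 3 CpG-A libraries against a control mean of 1.88, and was not called (log2 difference 6.32, SE 1.78, adjusted p = 0.104). Ifna4 was not called either (4.06, SE 0.981, adjusted p = 0.0559), nor was Ifna2, which was listed at 0 in control and averaged 123 ± 119 FPKM with CpG-A. The other rises of at least 6.39 log2 units were Isg20, Lta, Ccl5, Ccl4 and Spp1. Of the 10 largest rises, 9 passed with any 1 library left out. Ccl5 was lost without CpG-A replicate 1 (adjusted p = 0.106), control replicate 1 (0.0808) or control replicate 2 (0.0691). Of the 10 largest falls, Cd209a, Ifitm2 and Cd244 passed with any 1 library left out, and the other 7 (Sepp1, Tmem223, Tmem107, S100a4, Id3, Vkorc1 and Il12a) did not, with a highest adjusted p between 0.0572 and 0.153. From the set followed throughout, Siglech, Tcf4, Tlr9, Myd88, Bst2, H2-Ab1 and Ciita were not called with CpG-A (log2 differences between -0.49 and 0.57), nor were Il6 (4.18, adjusted p = 0.125), Il12b (1.93, 0.505), Cd274 (2.42, 0.0798) and Ccr7 (1.53, 0.584). Isg15, Ifit1, Ccl3 and Cd86 rose. Tnf rose as well (4.60, adjusted p = 0.0321) but lost the call without CpG-A replicate 1 (0.153), CpG-A replicate 2 (0.0749), control replicate 2 (0.131) or control replicate 3 (0.109), and Irf7 (3.27, adjusted p = 0.0107) lost it without CpG-A replicate 3 (0.0595).

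With CpG-A 171 genes were called, 122 higher and 49 lower, and 13 of them were provider-named. Among other settings, there were 94 higher and 26 lower without CpG-A replicate 1 and 97 and 27 without control replicate 2. Adding 0.01 gave 101 and 22, and a term for the replicate number 191 and 94. Without the 4 libraries numbered 1, chosen after seeing the data, there were 92 and 18. At an unadjusted p below 0.05 there were 1495 genes (12.8%). The samples of the groups did not overlap for 1948 genes (16.7%, where chance gives 10%). Scaling the libraries by median-of-ratios factors or to a common upper quartile moved the median of all genes by 0.157 and 0.136 with CpG-A, by 0.256 and 0.228 with CpG-B and by 0.147 and 0.155 with CpG-C, so log2 differences against control are relative to a median of -0.272, -0.255 and -0.223.

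Of the fixed lists, 13 of 20 pathway lists were called by camera with CpG-A, 9 of them also with an estimated correlation, and fry called 12. Interferon-stimulated genes rose in 28 of 50 members and fell in 0 (44 higher when adjusted over the list alone, camera adjusted p = 5.19e-72, 0.00238 with an estimated correlation), and 27 to 33 rose with any 1 library left out. Type I and III interferons rose in 2 of 12 (11 adjusted over the list alone, 3.22e-15, 0.0264 with an estimated correlation), with 5 of the 12 listed at 0 in all control libraries. The number rising was 10 without CpG-A replicate 2 and 4 without CpG-B replicate 2. NF-kB pathway and targets rose in 3 of 25 (7 adjusted over the list alone, 9.09e-08), maturation and co-stimulation in 3 of 22 (5 up and 1 down over the list alone, 5.71e-07), chemokines and their receptors in 4 of 15 (4 and 1; 0.000357), negative feedback in 3 of 24 (3; 0.000128) and apoptosis and survival in 3 of 30 (3 and 1; 0.002). The cytokine rises numbered 3 without CpG-C replicate 1 or 2 and 0 without CpG-A replicate 1 or control replicate 2. Ribosomal protein falls numbered 4 without CpG-B replicate 2, 1 without CpG-B replicate 1 or 3, CpG-C replicate 2 or control replicate 3, and 0 without CpG-A replicate 1 or 3 or control replicate 1 or 2. The NF-kB count was 1 without CpG-A replicate 1 or 3, any CpG-B replicate, CpG-C replicate 3, or control replicate 1 or 2. Inflammatory cytokines were higher as a list with 1 rise (Tnf) and 1 fall (Il12a) among 16 (4 and 1 over the list alone, 4.29e-05), and stress and dissociation genes with 0 of 12 passing (0.00619; 0.0799 with a filter at 5 FPKM and 0.0647 without the 4 libraries numbered 1, both chosen after seeing the data). These lists held with an estimated correlation (adjusted p between 0.00609 and 0.0479). MHC class I presentation (1 of 22 rose, 8 adjusted over the list alone, 2.54e-10) had an adjusted p = 0.0544 with an estimated correlation, cholesterol synthesis and uptake (0 of 26, 1 over the list alone, 4.49e-05) 0.287, and the unfolded protein response (0 of 30, 1 over the list alone, 9.63e-05) 0.11. Ribosomal proteins were lower as a list (2 of 76 fell; 1 up and 36 down over the list alone, 2.65e-15, 0.159 with an estimated correlation).

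The remaining pathway lists were not called with CpG-A: plasmacytoid identity (1 of 38 fell, 1 over the list alone, adjusted p = 0.701), MHC class II presentation (1 of 15 fell; 0.954), TLR9 signalling (3 of 26 rose; 0.102, 0.0482 under either scaling and 0.0459 without a filter), fatty acid oxidation (0 of 21; 0.173), glycolysis (0 of 20; 0.907), oxidative phosphorylation (0 of 56; 0.808) and cell cycle (0 of 39; 0.277). Among cell type lists, natural killer cells (1 of 11 rose, Ncr1; adjusted p = 0.0318) and progenitors (1 of 6 rose, Ly6a; 0.0347) were called, neither with an estimated correlation (0.252 and 0.255). Natural killer cells lost the call without CpG-A replicate 2 (0.0623) or control replicate 2 (0.203), and progenitors without CpG-A replicate 1 (0.495) or control replicate 2 (0.106), under upper quartile scaling (0.0543) and without a filter (0.128). Of the tests chosen after seeing the data, progenitors lost it with library weights (0.126), a filter at 5 FPKM (0.0572) and without the 4 libraries numbered 1 (0.61). Erythroid cells were called higher with the weights (0.023) and without those 4 libraries (0.00879), and B cells and plasma cells lower (0.0404 and 0.0204). The simulated recovery for this comparison was 28% at a change of 2 log2 units, so most simulated changes of that size went uncalled.

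The same question for CpG-B gave the largest number of calls. Siglech (gene 233274, chromosome 7, 55768184 to 55779451), a surface lectin typical of mouse plasmacytoid dendritic cells, fell from 2721 ± 551 FPKM in control to 196 ± 80.3 FPKM with CpG-B (SD, n = 3 per group; log2 difference -3.87, SE 0.411, limma adjusted p = 4.77e-05). The interleukin 1 receptor antagonist Il1rn (gene 16181, chromosome 2, 24336860 to 24351491) rose from 0.13 ± 0.142 to 689 ± 273 FPKM (log2 difference 9.19, SE 0.851, limma adjusted p = 1.57e-05). The cytokine gene Il6 rose from 0.193 ± 0.19 to 502 ± 282 FPKM (8.55, SE 1.23, adjusted p = 0.000687), and Il12b, a subunit of interleukin 12, from 0.05 ± 0.0624 to 100 ± 29.8 FPKM (6.54, SE 1.14, adjusted p = 0.00292). Ccr7, a receptor that guides mature dendritic cells to lymph nodes, rose from 9.81 ± 9.02 to 453 ± 164 FPKM (5.98, SE 1.06, adjusted p = 0.00315). Hamp (gene 84506, chromosome 7, 30942368 to 30944017), which encodes hepcidin, rose from 0.563 ± 0.598 to 1588 ± 1693 FPKM (9.44, SE 0.87, adjusted p = 1.57e-05).

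The 10 largest rises with CpG-B also held Bcl2a1d, Ccl4, Ccl3, Gzmb, Ebi3, Ccl5, Cxcl10 and Bcl2a1a, and the 10 largest falls were Cd209a, Rnase4, Tsc22d1, Ramp1, Gapt, Id3, Arl5c, Fcrla, Havcr1 and Atp1b1. All 20 passed with any 1 library left out. Il10 averaged 59.8 ± 55.3 FPKM and was listed at 0 in every control library. Isg15, Ifit1, Cd40, Cd86 and Cd274 rose (log2 differences between 3.83 and 7.56). Ifnb1 averaged 253 ± 245 FPKM and was not called (6.12, SE 1.78, adjusted p = 0.06), nor were Irf7 (2.13, 0.0583), Ifna4 (1.03, 0.634), Il12a (-1.64, 0.418), H2-Ab1, Ciita, Tlr9, Myd88 and Bst2 (log2 differences between -0.72 and 0.98). Ifna2 averaged 9.06 ± 14.8 FPKM, was listed at 0 in control and was not called. Tcf4, a transcription factor needed for the identity of these cells, fell (-2.60, adjusted p = 0.0176) but lost the call without CpG-B replicate 1 (0.085), CpG-B replicate 3 (0.051), control replicate 2 (0.0848) or control replicate 3 (0.0789). Tnf rose (4.23, 0.0221) and lost the call without CpG-B replicate 2 (0.0608), CpG-B replicate 3 (0.103), control replicate 2 (0.101) or control replicate 3 (0.0852).

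CpG-B changed 669 genes, 380 higher and 289 lower, 66 of them provider-named. The higher share of 56.8% became 69.8% (470 and 203) under median-of-ratios scaling and 70.9% (480 and 197) under upper quartile scaling. It was 50.3% (535 and 528) with library weights and 50.4% (323 and 318) without the 4 libraries numbered 1, both chosen after seeing the data. At an unadjusted p below 0.05 there were 2161 genes (18.6%), and 2991 genes (25.7%, chance 10%) did not overlap. The count fell to 343 without CpG-B replicate 1, 365 without CpG-B replicate 2, 442 without CpG-B replicate 3 and 381 without control replicate 2.

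With CpG-B 14 of 20 pathway lists were called, 8 of them also with an estimated correlation, and fry called 13. Interferon-stimulated genes rose in 32 of 50 members (38 adjusted over the list alone, camera adjusted p = 4.46e-45, 0.00298 with an estimated correlation), and in 28 to 33 with any 1 library left out. Maturation and co-stimulation rose in 13 of 22 (15 adjusted over the list alone, 8.8e-16), and in 6 without CpG-B replicate 1 or 2 and 7 without CpG-B replicate 3. Inflammatory cytokines rose in 9 of 16 (11; 7.81e-13), NF-kB pathway and targets in 6 of 25 (11; 4.8e-10), negative feedback in 6 of 24 (10; 7.8e-06), chemokines and their receptors in 7 of 15 with 1 fall (8 up and 3 down over the list alone, 7.04e-05), apoptosis and survival in 7 of 30 with 1 fall (10 and 1; 2.21e-06) and stress and dissociation in 2 of 12 (4; 0.000433). The negative feedback count was 3 without CpG-B replicate 2 or 3. These lists held with an estimated correlation (adjusted p between 0.00247 and 0.0167). Plasmacytoid dendritic cell identity was lower: 17 of 38 members fell and 0 rose (19 down over the list alone, camera adjusted p = 2.2e-12), 13 to 17 fell with any 1 library left out, and the adjusted p = 0.0554 with an estimated correlation. With a term for the replicate number, given below, the identity list was called with an estimated correlation too. Among the members, Upb1 (-5.01), Smim5 (-5.10), Klk1b27 (-4.88) and Atp1b1 (-5.64) fell most in the set named by rule. In the same libraries the natural killer cell list was higher, with 4 of 11 rising (7 over the list alone, adjusted p = 2.32e-06, 0.0523 with an estimated correlation).

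MHC class I presentation rose in 5 of 22 (10 over the list alone, 5.57e-11, 0.0535 with an estimated correlation), the unfolded protein response in 5 of 30 (8; 8.79e-05, 0.103), cell cycle in 2 of 39 (2; 1.91e-05, 0.092), type I and III interferons in 0 of 12 (1; 0.00551, 0.347) and glycolysis in 0 of 20 (3; 0.011, 0.236), so these CpG-B calls were lost with an estimated correlation. The MHC class I count was 2 without CpG-B replicate 1 or control replicate 2 and 3 without CpG-B replicate 2 or 3, CpG-A replicate 3 or CpG-C replicate 3. The unfolded protein count was 2 without CpG-B replicate 2 or 3 or control replicate 2, and 3 without control replicate 1 or 3, CpG-A replicate 3 or CpG-C replicate 3. The interferon list lost its call without CpG-B replicate 2 (0.0552), and glycolysis without CpG-B replicate 1 (0.0649) or control replicate 2 (0.0547). Lists not called were MHC class II presentation (1 rose and 1 fell of 15; adjusted p = 0.0931), TLR9 signalling (2 rose and 3 fell of 26; 0.204), ribosomal proteins (1 and 1 of 76; 0.171), oxidative phosphorylation (1 of 56 rose; 0.192), fatty acid oxidation (1 of 21 fell; 0.694) and cholesterol synthesis and uptake (1 of 26 rose; 0.16). Ribosomal proteins (0.000357 and 0.000305), oxidative phosphorylation (0.000984 and 0.00095) and MHC class II presentation (0.0378 and 0.0394) were called higher under median-of-ratios and upper quartile scaling. Of the tests chosen after seeing the data, library weights called ribosomal proteins higher (0.00901), and leaving out the 4 libraries numbered 1 MHC class II presentation (0.0105) and oxidative phosphorylation (0.0273).

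The other cell type lists with CpG-B gave erythroid cells (1 of 4 rose, Car2; adjusted p = 0.0187), T cells (2 rose and 1 fell of 11; 0.0222) and neutrophils (1 of 3 rose, Lcn2, listed at 0 in control; 0.0498), none called with an estimated correlation (0.0982, 0.0975 and 0.228). Erythroid cells lost the call without CpG-A replicate 3 (0.0514), CpG-B replicate 3 (0.0506) or control replicate 2 (0.0626) and without a filter (0.128), and T cells without CpG-A replicate 3 (0.0582) or control replicate 2 (0.082) and with a filter at 5 FPKM, chosen after seeing the data (0.106). Neutrophils lost it without CpG-A replicate 1 (0.0561) or 3 (0.0623), CpG-C replicate 1 (0.058), control replicate 1 (0.0998) or control replicate 2 (0.108), under either scaling (0.0723 and 0.0697), with 0.01 added (0.0698) and without a filter (0.907), and also with library weights (0.162) or quantile normalization (0.0799), both chosen after seeing the data. Conventional dendritic cells (3 rose and 4 fell of 12; 0.0589), B cells and plasma cells (1 of 7 fell; 0.157), monocytes and macrophages (0 of 6; 0.409) and progenitors (1 of 6 rose; 0.157) were not called. Conventional dendritic cell genes rising numbered 1 without CpG-B replicate 1 or 2 or control replicate 2 or 3, and those falling 2 without CpG-B replicate 1. That list was called lower under median-of-ratios (0.0364) and upper quartile scaling (0.043), and, chosen after seeing the data, under quantile normalization (0.0319), with a filter at 5 FPKM (0.0275) and without the 4 libraries numbered 1 (0.0101).

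**Figure D2:**
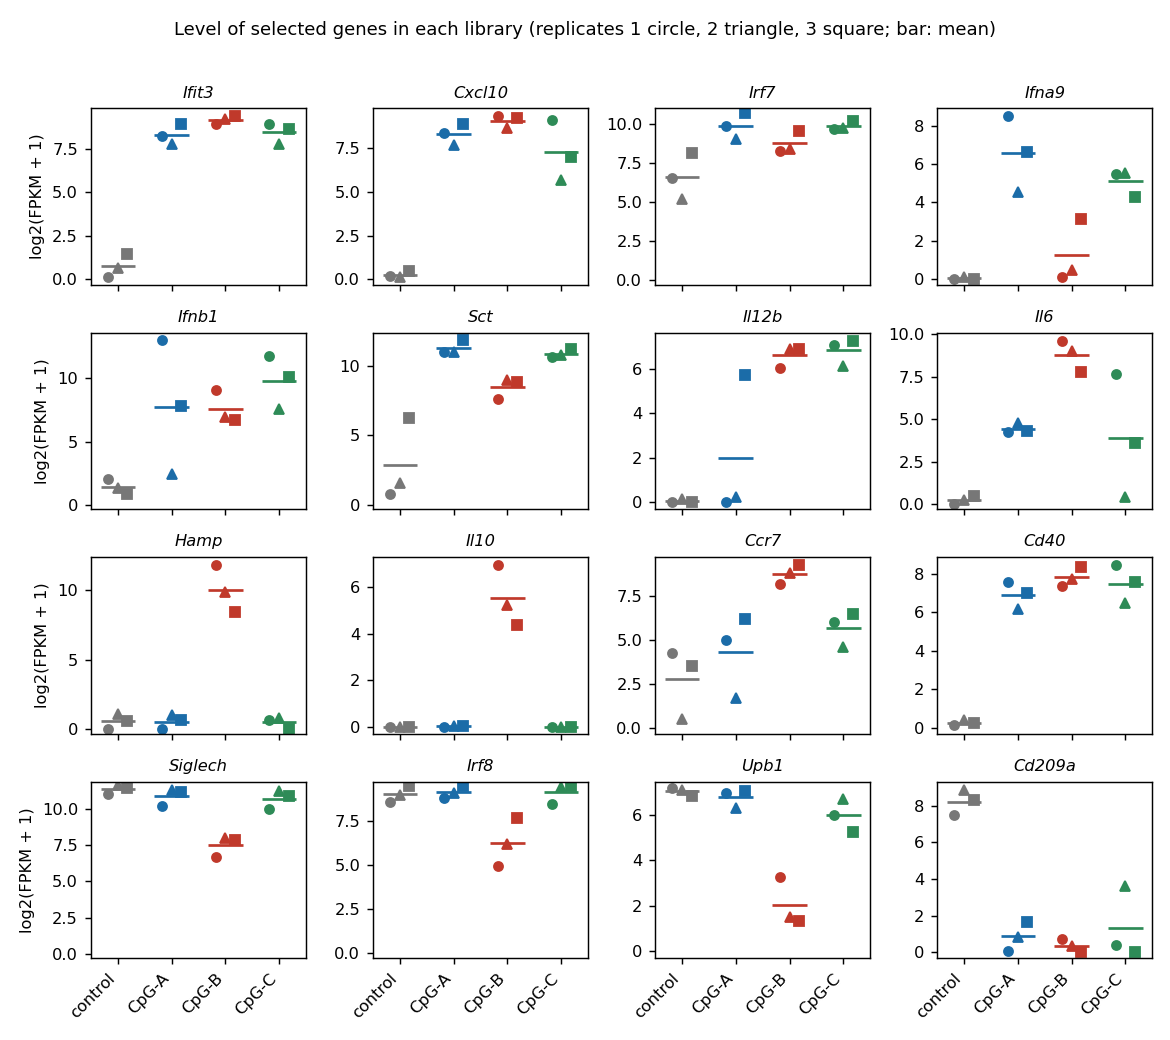
Levels of 16 genes in each of the 12 libraries, by group, as log2 of FPKM after adding 1. Siglech averaged 196 FPKM with CpG-B and between 1789 and 2721 FPKM in the other groups.

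CpG-C was compared with control in the same way. The chemokine gene Ccl4 rose most, from 30.2 ± 9.09 to 15620.5 ± 9074 FPKM (SD, n = 3 per group; log2 difference 8.83, SE 0.636, limma adjusted p = 3.94e-06). Lymphotoxin alpha, Lta, rose from 0.633 ± 0.481 to 752 ± 476 FPKM (8.60, SE 0.962, adjusted p = 0.00013). Tnf rose from 9.33 ± 15.1 to 330 ± 157 FPKM (6.24, SE 1.01, adjusted p = 0.00325), and Il12b from 0.05 ± 0.0624 to 119 ± 43.5 FPKM (6.76, SE 1.14, adjusted p = 0.00458). Ifit3 reached 367 ± 138 FPKM (7.69, SE 0.473) and Sct 1867 ± 417 FPKM (7.99, SE 0.963). Cd209a fell to 3.91 ± 6.49 FPKM (-6.88, SE 0.959, adjusted p = 0.000953). Cd7, a surface protein of these cells, fell from 2328 ± 661 to 418 ± 35.8 FPKM (-2.44, SE 0.357, adjusted p = 0.00144).

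Ifnb1 rose with CpG-C (8.35, SE 1.78, adjusted p = 0.0242), with 3405, 189 and 1074 FPKM in the 3 libraries. Its call was lost without CpG-C replicate 1 (adjusted p = 0.12), CpG-C replicate 3 (0.0909), control replicate 1 (0.0606), control replicate 2 (0.0762) or control replicate 3 (0.0707). The other 9 of the 10 largest rises, which included Ccl3, Xcl1, Bcl2a1d, Cd40 and Isg20, passed with any 1 library left out. Of the 10 largest falls, Cd209a, Mgst3, Ankrd37, Iqcc and Pstk did so, and Id3, Sepp1, Rnase4, Gstm5 and Cd244 did not, with a highest adjusted p between 0.0692 and 0.182. Isg15, Ifit1 and Cxcl10 rose. Irf7 rose (3.23, 0.0117) and lost the call without CpG-C replicate 3 (0.0658), and Cd86 rose (3.77, 0.0138) and lost it without CpG-C replicate 1 (0.0506) or 3 (0.08). Il6 (3.64, 0.189), Ccl5 (5.30, 0.0555), Il12a (-2.30, 0.354), Ccr7 (2.93, 0.229), Cd274 (2.03, 0.147), Ifna4 (0.43, 0.912), Siglech (-0.67, 0.537), Tcf4 (-0.36, 0.859), H2-Ab1, Ciita, Tlr9, Myd88 and Bst2 were not called. Ifna2 averaged 70.9 ± 67.3 FPKM, was listed at 0 in control and was not called.

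CpG-C changed 217 genes, 156 higher and 61 lower, 21 of them provider-named. Median-of-ratios scaling gave 182 higher and 40 lower, and upper quartile scaling 189 and 40. There were 88 and 20 without CpG-C replicate 3, 103 and 23 without control replicate 2, and 208 and 102 with a term for the replicate number. Library weights, chosen after seeing the data, gave 253 and 153. At an unadjusted p below 0.05 there were 1473 genes (12.7%), and 2081 genes (17.9%, chance 10%) did not overlap. The count fell to 119 without CpG-C replicate 1, 108 without CpG-C replicate 3 and 126 without control replicate 2. Of the 20 pathway lists 15 were called, 7 of them also with an estimated correlation, and fry called 12. Interferon-stimulated genes rose in 32 of 50 members (43 adjusted over the list alone, camera adjusted p = 3.56e-67, 0.00302 with an estimated correlation), and in 25 to 32 with any 1 library left out. NF-kB pathway and targets rose in 5 of 25 (11 up and 1 down over the list alone, 2.91e-09), inflammatory cytokines in 3 of 16 (6; 1.38e-06), maturation and co-stimulation in 2 of 22 (5; 8.18e-07), negative feedback in 2 of 24 (5; 1.7e-05), chemokines and their receptors in 3 of 15 (5; 4.85e-05) and apoptosis and survival in 4 of 30 (5 and 1; 0.000948), and these held with an estimated correlation (adjusted p between 0.00302 and 0.0296). The NF-kB count was 2 without CpG-C replicate 1 or 3 or control replicate 2 and 3 without CpG-C replicate 2, and the cytokine count was 5 without CpG-C replicate 2. The maturation count was 1 without CpG-C replicate 1 or 3.

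The other called lists with CpG-C were lost with an estimated correlation: MHC class I presentation (3 of 22 rose, 8 over the list alone, 2.91e-09, then 0.0767), type I and III interferons (2 of 12 rose, 3 over the list alone, 4.85e-05, then 0.172), the unfolded protein response (0 of 30, 1 over the list alone, 6.45e-05, then 0.113), cholesterol synthesis and uptake (0 of 26; 0.000957, then 0.37), TLR9 signalling (2 of 26 rose; 0.0362, then 0.332) and stress and dissociation (1 of 12 rose; 0.039, then 0.113) were higher. Ribosomal proteins (1 of 76 fell, 1 up and 15 down over the list alone, 4.29e-12, then 0.205) and fatty acid oxidation (1 of 21 fell; 0.0161, then 0.0577) were lower. The interferon count was 0 without CpG-C replicate 1 and 1 without CpG-C replicate 2 or 3 or any control replicate. The MHC class I count was 0 without CpG-C replicate 1 or control replicate 2 and 1 without CpG-C replicate 3. TLR9 signalling lost its call without CpG-C replicate 2 (0.157), control replicate 1 (0.0603) or control replicate 2 (0.0502), fatty acid oxidation without control replicate 1 (0.0539), and stress and dissociation without CpG-C replicate 1 (0.0949) or 2 (0.0522), control replicate 1 (0.101) or control replicate 2 (0.0595) and without a filter (0.055). With the tests chosen after seeing the data, stress lost it under quantile normalization (0.0641), with library weights (0.0765), with a filter at 5 FPKM (0.0576) and without the 4 libraries numbered 1 (0.184), and TLR9 signalling with the filter at 5 FPKM (0.0746). Identity (2 of 38 fell; adjusted p = 0.708), MHC class II presentation (1 of 15 fell; 0.637), cell cycle (0 of 39; 0.413), glycolysis (0 of 20; 0.808) and oxidative phosphorylation (0 of 56; 0.115) were not called, nor was any of the 8 cell type lists (natural killer cells 1 up and 1 down of 11; 0.179). Oxidative phosphorylation was called lower with 0.01 added (0.0483) and without a filter (0.0377), and progenitors higher with 0.01 added (0.0456).

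**Figure D3:**
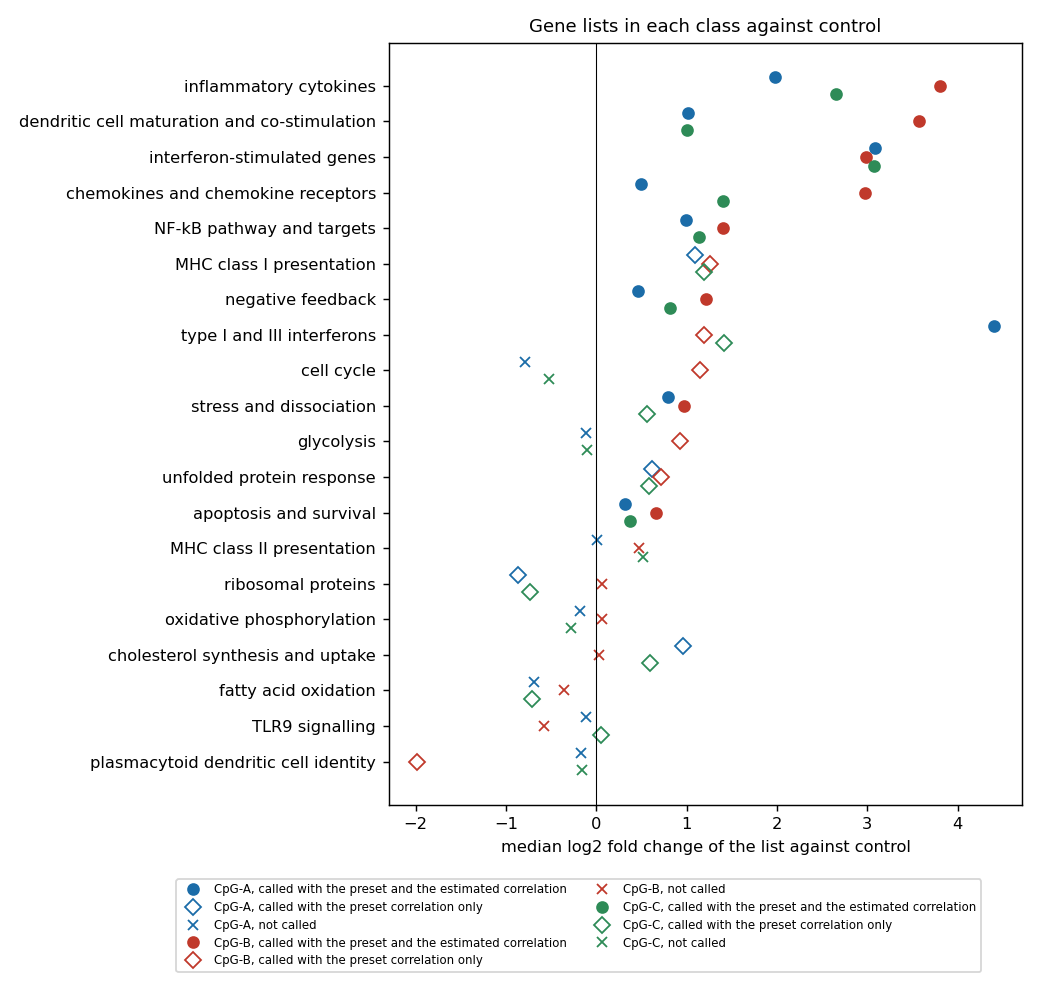
Median log2 difference from control of each pathway list for the 3 classes, with symbols for lists called with the preset and the estimated correlation, with the preset correlation only, or not called. The identity list was called lower with CpG-B (adjusted p = 2.2e-12) and not with CpG-A (0.701) or CpG-C (0.708).

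The responses to the 3 classes overlapped. Of 767 genes called in at least 1 class, 89 were higher and 16 lower in all 3, and 0 went in opposite directions in any pair. Of the 122 genes higher with CpG-A, 105 were also higher with CpG-C and 97 with CpG-B, and CpG-B and CpG-C shared 111. Lower genes were shared by CpG-A and CpG-C in 24 cases, by CpG-A and CpG-B in 24 and by CpG-B and CpG-C in 34. Overlaps of independent lists of these sizes would be 1.63, 3.98 and 5.09 for higher and 0.257, 1.22 and 1.51 for lower genes, which leaves out the shared controls. In 100 simulations without a response but with the shared controls, no gene was called in both of any pair. Taking instead as many of the most extreme simulated genes as were called in each direction, a test chosen after seeing the data, gave mean overlaps of 23.4, 39.6 and 46.8 higher genes and 7.45, 17.4 and 20.3 lower genes. The highest were 34, 48 and 64 higher and 13, 25 and 31 lower, so the 24 lower genes of CpG-A and CpG-B lay within that range. The simulated noise was independent for each gene and library, so for real genes that vary together these ranges may be too narrow. They do not show that the other overlaps exceed what the shared controls give. Genes taken in opposite directions averaged at most 0.26, so the 0 opposite calls did not stand apart from the simulations. The 3 control libraries are too few to split, and part of each overlap may come from the shared controls. These libraries alone also give responses that correlate across genes, with a mean Pearson r of 0.5 in 100 simulations without a response. The observed r across the 11641 genes, which are not independent replicates, was 0.576 for CpG-A and CpG-B, 0.744 for CpG-A and CpG-C and 0.646 for CpG-B and CpG-C (Spearman 0.527, 0.683 and 0.591). The covariance of the responses was 1.08, 1.16 and 1.22 against 0.39 simulated. The number called in all 3 classes in the same direction, 105, lay between 75 and 115 with any 1 library left out.

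CpG-A and CpG-B were then compared with each other to test where the classes differed. Siglech was higher with CpG-A, 2017 ± 706 against 196 ± 80.3 FPKM (SD, n = 3 per group; log2 difference 3.39, 95% interval 2.51 to 4.27, limma adjusted p = 0.00068). Tsc22d1, a regulator of transcription, was 255 ± 68 FPKM with CpG-A and 2.62 ± 3.87 with CpG-B (6.65, 4.90 to 8.39). Hamp was 0.533 ± 0.507 FPKM with CpG-A and 1588 ± 1693 with CpG-B (-9.45, -11.30 to -7.59, adjusted p = 0.000206), and Il1rn 0.67 ± 1.02 against 689 ± 273 FPKM (-8.78, -10.60 to -6.97). The tryptophan-degrading enzyme Ido1 was 1.51 ± 2.46 FPKM with CpG-A and 181 ± 63.6 with CpG-B (-6.56, -8.56 to -4.56, adjusted p = 0.00205).

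Havcr1, Rgs10 and Smim5 were also among the 5 genes furthest above CpG-B, and Ifitm2, Tnip3 and Wfdc21 among the 5 furthest below. Clec10a (6.15, adjusted p = 0.0215) was the only one of the 10 lost with 1 library left out: CpG-A replicate 1 (0.0584) or 3 (0.0843), or CpG-B replicate 1 (0.0828), 2 (0.0593) or 3 (0.0617). Ifna12 was higher with CpG-A (3.51, adjusted p = 0.0109; 0.0683 without CpG-B replicate 1), as was Ifna9 (5.31, 0.0117; 0.0536 without CpG-A replicate 1 and 0.0766 without CpG-B replicate 1). Ccl3 was lower with CpG-A (-3.87, adjusted p = 0.0185) but not without CpG-A replicate 2 (0.0916), CpG-A replicate 3 (0.076) or CpG-B replicate 1 (0.11). Ccr7 (-4.45, adjusted p = 0.0393) and Il12b (-4.62, 0.0468) were lower and Tcf4 (2.40, 0.0492) higher with CpG-A, and each lost its call in most of the fits without 1 library. Ccr7 lost it without CpG-A replicate 1 (0.066) or 2 (0.139), CpG-B replicate 1 (0.11), 2 (0.108) or 3 (0.126), CpG-C replicate 3 (0.0541) or control replicate 3 (0.0503). Il12b lost it without any library but CpG-A replicate 3 (CpG-A replicates 0.149 and 0.174, CpG-B replicates 0.134, 0.134 and 0.138, CpG-C replicates 0.0557, 0.0601 and 0.0708, control replicates 0.0519, 0.0589 and 0.0604). Tcf4 lost it without any library but CpG-C replicate 1 and control replicate 1 (CpG-A replicates 0.054, 0.171 and 0.13, CpG-B replicates 0.228, 0.0609 and 0.12, CpG-C replicates 2 and 3 0.0589 and 0.072, control replicates 2 and 3 0.0603 and 0.0602). Ifnb1 (0.20, adjusted p = 0.993), Il6 (-4.37, 0.0831), Isg15 (-0.80, 0.729), Ifit1 (-0.87, 0.591) and Cxcl10 (-0.75, 0.696) were not called different.

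CpG-A and CpG-B differed in 283 genes, 115 higher and 168 lower with CpG-A, 26 of them provider-named. The share higher with CpG-A was 36.8% and 31% under median-of-ratios and upper quartile scaling (93 and 207 under the second), and without the 4 libraries numbered 1, chosen after seeing the data, there were 134 higher and 96 lower. At an unadjusted p below 0.05 there were 1639 genes (14.1%), and 2291 (19.7%, chance 10%) did not overlap. The count was 173 without CpG-A replicate 1, 137 without CpG-A replicate 2, 170 without CpG-A replicate 3, 62 without CpG-B replicate 1, 155 without CpG-B replicate 2 and 169 without CpG-B replicate 3, where the majority turned (99 higher and 70 lower). Pathway lists were called in 12 of 20 cases, 4 of them with an estimated correlation (identity, cytokines, maturation, and apoptosis and survival, adjusted p = 0.0478 for each), and fry called 10.

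Identity genes were higher with CpG-A in 14 of 38 (23 up and 1 down over the list alone, camera adjusted p = 1.24e-19), and in 7 without CpG-A replicate 2 or CpG-B replicate 1 and 8 without CpG-A replicate 3. Higher with CpG-A were also type I and III interferons (2 of 12, 4 over the list alone, 1.58e-06), TLR9 signalling (3 of 26; 0.00253) and cholesterol synthesis and uptake (0 of 26; 0.0329). Lower with CpG-A were ribosomal proteins (3 of 76, 32 over the list alone, 3.67e-20), cell cycle (3 of 39, 1 up and 13 down; 7.43e-09), inflammatory cytokines (4 of 16, 9; 1.33e-06), maturation and co-stimulation (5 of 22, 1 up and 6 down; 2.49e-06), apoptosis and survival (3 of 30, 8; 0.00309), glycolysis (0 of 20; 0.0123), chemokines and their receptors (1 higher and 3 lower of 15; 0.0158) and NF-kB pathway and targets (1 of 25; 0.0329). Chemokines lost the call without CpG-A replicate 2 (0.0772) or CpG-B replicate 2 (0.0536), and glycolysis without CpG-A replicate 2 (0.0772) or CpG-B replicate 1 (0.0601). Cholesterol lost it without CpG-A replicate 2 (0.0851), CpG-A replicate 3 (0.32) or CpG-B replicate 1 (0.156), and NF-kB without CpG-A replicate 2 (0.0772), CpG-A replicate 3 (0.0698), CpG-B replicate 1 (0.0516) or CpG-B replicate 2 (0.0664). Adding 0.1 instead of 1 also ended the calls of cholesterol (0.0508) and NF-kB (0.0737), and adding 0.01 that of NF-kB (0.104). Interferons lost the call without the 4 libraries numbered 1, chosen after seeing the data (0.0657). Counts of maturation genes were 1 without CpG-B replicate 1 or 2 and 2 without CpG-B replicate 3, and counts of cytokines 2 without CpG-A replicate 2 or CpG-B replicate 2 and 1 without CpG-B replicate 1. Counts of apoptosis genes were 1 without CpG-A replicate 2 or 3 or CpG-B replicate 2 or 3, 0 without CpG-B replicate 1 and 5 without control replicate 1, and counts of cell cycle genes 0 without CpG-A replicate 1 or 2 or CpG-B replicate 1 and 1 without CpG-B replicate 2 or 3. Interferon genes numbered 4 without CpG-A replicate 2, 1 without CpG-A replicate 1 and 0 without CpG-B replicate 1. Lower chemokine genes numbered 0 without CpG-A replicate 2 or CpG-B replicate 1 and 1 without CpG-A replicate 3 or CpG-B replicate 2. Ribosomal protein genes numbered 0 without CpG-A replicate 1 or CpG-B replicate 1 or 3, 1 without CpG-A replicate 2, CpG-C replicate 3 or control replicate 2, 10 without CpG-B replicate 2 and 7 without CpG-C replicate 1, and TLR9 signalling genes 1 without CpG-B replicate 1. Under median-of-ratios and upper quartile scaling MHC class II presentation (0.0401 and 0.0374) and oxidative phosphorylation (0.0109 and 0.00687) were also called lower with CpG-A, and under the second MHC class I presentation (0.0399). Without a filter MHC class II presentation (0.0296), oxidative phosphorylation (0.0279), stress and dissociation (0.0254) and T cells (0.0289) were called lower. Of the tests chosen after seeing the data, library weights and leaving out the 4 libraries numbered 1 called MHC class I (0.0253 and 0.013), MHC class II (0.00943 and 1.04e-05), oxidative phosphorylation (0.0332 and 0.0402) and the unfolded protein response (0.0188 and 0.000703) lower. The second also called stress lower (0.031) and conventional dendritic cells higher (0.00848), and a filter at 5 FPKM oxidative phosphorylation lower (0.0493). With an estimated correlation the lost lists had an adjusted p = 0.132 for interferons, ribosomal proteins and NF-kB, 0.203 for TLR9 signalling, 0.554 for cholesterol, 0.0545 for cell cycle, 0.231 for glycolysis and 0.122 for chemokines. Interferon-stimulated genes were not called (0 of 50; adjusted p = 0.536). Natural killer cells were lower with CpG-A (1 of 11; 0.00175, 0.211 with an estimated correlation).

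The difference between CpG-A and CpG-C was tested in the same fit. Il12b averaged 17.6 ± 30.3 FPKM with CpG-A and 119 ± 43.5 with CpG-C (SD, n = 3 per group; log2 difference -4.83, 95% interval -7.26 to -2.40, limma adjusted p = 0.726). Ifna4 was 25.3 ± 27.6 FPKM with CpG-A and 0.55 ± 0.953 with CpG-C (3.63, 1.53 to 5.72), and Ccl3 2734 ± 3715 against 9530 ± 6966 FPKM (-2.57, -4.26 to -0.87), neither of which passed. Siglech (0.19, -0.69 to 1.06), Isg15 (-0.69, -2.37 to 1.00) and Ifit1 (-0.10, -1.42 to 1.21) differed little beside their intervals.

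No gene was called between CpG-A and CpG-C by limma (0 of 11641; smallest adjusted p = 0.63), with 467 genes (4.01%) at an unadjusted p below 0.05 and 825 genes (7.09%, chance 10%) not overlapping. Without CpG-A replicate 3 there were 2 genes, and without CpG-C replicate 2 there was 1. The median absolute log2 difference was 0.493 against a median SE of 0.841, and the self-test for this comparison recovered 26% of changes of 2 log2 units and 80% of 4. Genes near the minimum were not among those changed in the self-test. Camera called 1 of 20 pathway lists: type I and III interferons were higher with CpG-A (0 of 12 passed, 6 over the list alone, adjusted p = 5.57e-08). The call was lost with an estimated correlation (0.656) and without CpG-A replicate 1 (0.0507), and fry called 0 lists. Without CpG-A replicate 1 there were 3 called lists, without CpG-C replicate 2 there were 4, and without CpG-C replicate 3 there were 2. Natural killer cells were called higher with CpG-A with library weights (0.0151) and without the 4 libraries numbered 1 (0.00126), both chosen after seeing the data.

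CpG-B and CpG-C share a full phosphorothioate backbone and were compared last. Siglech was 196 ± 80.3 FPKM with CpG-B and 1789 ± 691 with CpG-C (SD, n = 3 per group; log2 difference -3.20, 95% interval -4.08 to -2.33, limma adjusted p = 0.00216). Hamp was 1588 ± 1693 FPKM with CpG-B against 0.46 ± 0.403 (9.50, 7.65 to 11.36, adjusted p = 0.000203), and Il1rn 689 ± 273 against 2.15 ± 3.36 FPKM (8.23, 6.42 to 10.05). Tnfsf4, the ligand of a T cell co-stimulatory receptor, was 13 ± 8.11 FPKM with CpG-B and 0.02 ± 0.0173 with CpG-C (3.63, 2.40 to 4.85, adjusted p = 0.00536), and Il10, at 59.8 ± 55.3 FPKM with CpG-B, was listed at 0 in all CpG-C libraries. The cysteine protease gene Ctsl was lower with CpG-B (-2.27, -2.95 to -1.58, adjusted p = 0.003), as was Upb1 (-3.96, -5.19 to -2.72). Il6 was not called (4.91, 2.27 to 7.54, adjusted p = 0.0711), nor were Tnf, Il12b, Ifnb1 and Cxcl10.

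Of the 5 genes furthest above CpG-C, Hamp, Ifitm1, Tnip3, Il1rn and Emilin2, all passed with any 1 library left out. Of the 5 furthest below, Tsc22d1, Ldhb and Havcr1 did. Rgs10 was lost without CpG-C replicate 2 (0.0578), and Clec10a without CpG-B replicate 1 (0.124), 2 (0.0917) or 3 (0.0901) or CpG-C replicate 2 (0.169) or 3 (0.138). CpG-B and CpG-C differed in 157 genes, 91 higher and 66 lower with CpG-B, 20 of them provider-named. The higher share was 65.1% under median-of-ratios scaling (112 and 60) and 68% under upper quartile scaling (115 and 54), and without the 4 libraries numbered 1, chosen after seeing the data, there were 54 higher and 87 lower. At an unadjusted p below 0.05 there were 1379 genes (11.8%), and 2140 (18.4%, chance 10%) did not overlap. The count was 42 without CpG-B replicate 1, 76 without CpG-B replicate 2, 78 without CpG-B replicate 3, 37 without CpG-C replicate 2 and 72 without CpG-C replicate 3. The majority turned without CpG-B replicate 1 (18 higher and 24 lower), CpG-B replicate 2 (34 and 42), CpG-B replicate 3 (27 and 51) or CpG-C replicate 1 (74 and 76), and with a filter at 5 FPKM, chosen after seeing the data (55 and 65).

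Between CpG-B and CpG-C 10 of 20 pathway lists were called, 0 of them with an estimated correlation, and fry called 11. With a term for the replicate number, given below, identity, cell cycle, TLR9 signalling and maturation were called with an estimated correlation too. Identity was lower with CpG-B (11 of 38, 23 over the list alone, camera adjusted p = 3.77e-19, 0.058 with an estimated correlation), with 3 members lower without CpG-B replicate 1 or CpG-C replicate 3, 6 without CpG-B replicate 3 and 2 without CpG-C replicate 2. TLR9 signalling was lower too (3 of 26, 1 up and 4 down over the list alone, 0.000233, 0.129), with 1 member lower without CpG-B replicate 1 or 2 or CpG-C replicate 2 or 3. Higher with CpG-B were ribosomal proteins (0 of 76, 0 over the list alone, 3.17e-19, 0.129 with an estimated correlation; 30 of 76 with library weights, chosen after seeing the data), cell cycle (1 of 39, 10 up and 1 down over the list alone, 1.98e-09, 0.058), maturation and co-stimulation (3 of 22, 10; 1.97e-07, 0.058), inflammatory cytokines (4 of 16, 6; 6.32e-05, 0.0727), oxidative phosphorylation (0 of 56; 0.00136, 0.0697), apoptosis and survival (1 of 30, 4 and 1; 0.00727, 0.058), glycolysis (0 of 20; 0.00727, 0.199) and stress and dissociation (0 of 12; 0.044, 0.129). Oxidative phosphorylation lost the call under quantile normalization, chosen after seeing the data (0.347). Apoptosis lost the call without CpG-C replicate 2 (0.062) and glycolysis without CpG-B replicate 1 (0.0528) or CpG-C replicate 2 (0.054). Stress lost it without CpG-A replicate 1 (0.0614), CpG-B replicate 2 (0.0575) or 3 (0.0808), CpG-C replicate 2 (0.0827) or 3 (0.0946), or control replicate 1 (0.0546), and with a filter at 5 FPKM, chosen after seeing the data (0.0802). Cytokine counts were 1 without CpG-B replicate 1 or 2 and 2 without CpG-B replicate 3, CpG-C replicate 2 or 3, or control replicate 2 or 3, and maturation counts 0 without any CpG-B replicate and 1 without CpG-C replicate 2. Interferon-stimulated genes were not called (0 of 50; 0.611). MHC class I presentation was called higher with CpG-B under upper quartile scaling (0.0338). Without a filter cholesterol synthesis was called lower (0.0252) and fatty acid oxidation higher (0.046). Of the tests chosen after seeing the data, library weights and leaving out the 4 libraries numbered 1 called cholesterol lower (0.0102 and 0.00245) and MHC class I (0.00928 and 0.00508), MHC class II (0.0367 and 0.000291) and chemokines (0.0399 and 0.0158) higher. The weights also called fatty acid oxidation higher (0.0445), and leaving out those libraries the unfolded protein response (0.0256) and erythroid cells (0.00588) higher and conventional dendritic cells lower (0.00588). Natural killer cells (1 of 11 higher, 4 over the list alone, 9e-06, 0.0403 with an estimated correlation), T cells (0 of 11; 0.0056, 0.0403) and neutrophils (1 of 3; 0.0204, 0.181) were higher with CpG-B, the last not without a filter (0.465), nor under quantile normalization (0.0831) or with library weights (0.113), both chosen after seeing the data.

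Across the 283 genes that differed between CpG-A and CpG-B, the median position of CpG-C was 0.13 on a scale from 0 at CpG-A to 1 at CpG-B. CpG-C lay nearer to CpG-A for 256 genes (90.5%) and nearer to CpG-B for 27. In total 75 genes were higher and 60 lower with CpG-B than with both other classes, and these counts moved with single libraries: 11 and 20 without CpG-B replicate 1, 21 and 12 without CpG-C replicate 2, 25 and 36 without CpG-B replicate 2, 22 and 48 without CpG-B replicate 3, 40 and 25 without CpG-C replicate 3, 44 and 36 without CpG-A replicate 2, and 53 and 35 without CpG-A replicate 3. Adding 0.01 gave 39 and 39, and no filter 55 and 29. Library weights gave 175 and 164, leaving out the 4 libraries numbered 1 gave 30 and 80, and a filter at 5 FPKM 45 and 59, all chosen after seeing the data. Both comparisons hold the same CpG-B libraries, so part of these counts may come from them: in 100 simulations without a response, chosen after seeing the data, as many of the most extreme genes shared 12 to 32 higher and 5 to 23 lower. The median position of CpG-C in them lay between 0.43 and 0.55. Their noise was independent between genes and of equal spread in all libraries, so these ranges may be too narrow. They do not settle how far the observed values lie beyond chance. With any 1 library left out, 62 to 356 genes differed between CpG-A and CpG-B, the median position lay between 0.0599 and 0.206, and between 76.5% and 93.5% lay nearer to CpG-A.

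The authors' deposited q-values were below 0.05 for 14737 of 16458 genes with a q-value for CpG-A against control (89.5%), 15857 of 17441 for CpG-B (90.9%) and 14839 of 16537 for CpG-C (89.7%). Between classes they were below 0.05 for 90.3% (CpG-A and CpG-B), 88.3% (CpG-A and CpG-C) and 91.1% (CpG-B and CpG-C). All 171, 669, 217, 283 and 157 genes called by limma had a deposited q-value below 0.05 and the same direction as the deposited log2 ratio. The deposited values come from the same libraries. Of the tested genes with a q-value, 10967 of 11567, 11158 of 11627, 10966 of 11585, 11005 of 11624 and 11026 of 11618 were below 0.05 in these comparisons. Nearly any set of called genes would thus have passed, and the match says little about the calls.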

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

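The tests with robust moderation, library weights, quantile normalization, a filter at 5 FPKM and without the 4 libraries numbered 1 were chosen only after the data were seen. No named gene changed direction under any alternative in a comparison where the main or the alternative fit called it. Changes of direction in genes called by neither fit were not counted. Leaving out 1 library kept 3753 gene values on their side of the threshold, weakened 527 and strengthened 22. For lists the numbers were 1882, 46 and 52. These totals pool all such fits and include genes and lists called in neither fit. Named gene calls that passed every such fit were 26 of 45 for CpG-A, 65 of 84 for CpG-B and 28 of 52 for CpG-C against control. Between classes they were 16 of 45 for CpG-A against CpG-B and 13 of 32 for CpG-B against CpG-C. List calls did so in 13 of 15, 13 of 18, 12 of 15, 9 of 13 and 10 of 13 cases in that order. For CpG-A against CpG-C it was 0 of 1. Both scalings kept 349 and 348 of 362 gene values and ended 11 calls each. The estimated correlation ended 45 list calls, and the 123 of 168 lists it kept include those that neither test called.

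Adding 0.1 instead of 1 weakened 37 of 362 gene values and 2 of 168 lists, totals that include genes and lists called in neither fit. Adding 0.01 gave 150 genes for CpG-A against CpG-B and 90 for CpG-B against CpG-C. Without a filter on low values, where 21573 genes were tested, the counts were 102 (CpG-A), 440 (CpG-B) and 118 (CpG-C) against control, 157 for CpG-A against CpG-B and 92 for CpG-B against CpG-C. At an adjusted p below 0.01, a stricter threshold by construction, they were 97, 302 and 97 against control, 82 and 44. Fits of only the 6 samples compared, with fewer samples for the spread, gave 95 for CpG-A and 144 for CpG-C against control, 176 for CpG-A against CpG-B and 73 for CpG-B against CpG-C. Library weights gave 1063 for CpG-B and 406 for CpG-C against control, 509 for CpG-A against CpG-B and 587 for CpG-B against CpG-C. The causes of the moves with the added value, the filter and the weights were not tested.

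The labels do not pair the samples. Once group means were removed, 12 of 12 libraries correlated best with their own number. Between groups, r lay between 0.0607 and 0.17 in the 18 pairs with the same number and between -0.131 and 0.029 in the others. This is a hint from the data and no record of pairing. A term for the replicate number, which the main fit did not hold, moved the counts to 285 for CpG-A against control, 434 for CpG-A against CpG-B, 276 for CpG-B against CpG-C and 161 shared by the 3 classes. With that term and an estimated correlation, pathway lists lost without it were called: identity (adjusted p = 0.016), cell cycle (0.0261), TLR9 signalling (0.0261) and maturation (0.0473) for CpG-B against CpG-C, cell cycle (0.0321) and TLR9 signalling (0.0385) for CpG-A against CpG-B, identity (0.0112), MHC class I (0.0148) and cell cycle (0.0242) for CpG-B, MHC class I (0.0377) and cholesterol (0.0483) for CpG-A, and MHC class I (0.0321) for CpG-C against control. Natural killer and T cells between CpG-B and CpG-C were not (0.0867 each). With the preset correlation that term added calls of MHC class I (0.0288) and cholesterol (0.0469) for CpG-B against CpG-C, MHC class II (0.034) and oxidative phosphorylation (0.038) for CpG-A against CpG-B and MHC class II (0.0471) for CpG-B against control, where it ended that of neutrophils (0.0574). It gave 108 genes higher and 122 lower with CpG-B than with both other classes. Without the 4 libraries numbered 1, with fewer samples, CpG-A against control had 110 genes and CpG-A against CpG-C 2 lists. The ribosomal protein list there reversed between CpG-A and CpG-C, with a median of 0.17 (adjusted p = 0.00434) against -0.118, and the cause was not tested. With an estimated correlation 8, 7, 4, 0 and 0 pathway lists were called for CpG-B and CpG-C against control, CpG-A against CpG-B, CpG-A against CpG-C and CpG-B against CpG-C, and fry called 0 for CpG-A against CpG-C. Leaving out 1 library gave 343 to 764 genes for CpG-B and 108 to 239 for CpG-C against control, 62 to 356 for CpG-A against CpG-B, 0 to 2 genes and 1 to 4 lists for CpG-A against CpG-C, and 37 to 166 genes for CpG-B against CpG-C. These fits have fewer samples. Where only 1 or 2 members of a list passed, that number often moved when 1 library was left out. Tests made for read counts, with their normalizations, were not run because the values are FPKM, and the estimated depth of 22800000 to 28400000 fragments limits genes near 0.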

Other observations

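Of the tests in this part, those on splits of the samples were planned, and the tests of explanations and the gene groups below were chosen only after the results were seen. Guanylate-binding proteins and immunity-related GTPases, interferon-inducible defence genes, rose in 8 of 17 members with CpG-A, 14 with CpG-B and 8 with CpG-C (camera adjusted p = 2.44e-26, 1.82e-21 and 5.47e-24, and 0.000178, 0.000379 and 0.000252 with an estimated correlation). Iigp1 rose from 2.50 ± 2.38 FPKM in control to 219 ± 60.4, 108 ± 33.2 and 185 ± 48.6 FPKM (SD, n = 3 per group, log2 differences 6.21, 5.18 and 5.96, SE 0.549, limma adjusted p = 2.61e-05, 4.77e-05 and 3.18e-05). The PYHIN family of DNA-sensing proteins rose in 7, 6 and 6 of 10 members (camera adjusted p = 1.37e-23, 4.01e-12 and 7.35e-22). Gbp2, Gbp3 and Gbp7 of the first family and Mndal and Ifi204 of the second are also in the fixed list of interferon-stimulated genes. Both families thus partly repeat that list, and their p-values were adjusted over these families only. Neither family was called between classes (adjusted p = 0.324 and 0.0704 for CpG-A against CpG-B, 0.637 for both between CpG-A and CpG-C, 0.11 and 0.106 for CpG-B against CpG-C).

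Ido2, Kmo and Kynu, which encode enzymes of tryptophan breakdown, and Pdcd4 were also chosen after their values were seen. With CpG-B Ido2 rose from 0.02 FPKM in control to 109 ± 84.3 FPKM (log2 difference 6.48, SE 0.881, limma adjusted p = 0.000416), while the later enzymes Kmo (255 ± 51.7 to 31.1 ± 15.7 FPKM, -3.13, 0.00138) and Kynu (94.4 ± 69.3 to 1.57 ± 2.51 FPKM, -5.42, 0.000304) fell. Against CpG-C the differences were 6.43 for Ido2 (adjusted p = 0.0025), -2.57 for Kmo (0.0166) and -3.93 for Kynu (0.0124). Pdcd4 fell in all 3 classes, from 373 FPKM to 69.5, 26.1 and 57.2 FPKM (adjusted p = 0.0175, 0.000231 and 0.0081).

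Each pair of groups allows only 10 splits of its 6 samples, too few for a test. The real split gave 171, 669 and 217 genes for CpG-A, CpG-B and CpG-C against control, 283 for CpG-A against CpG-B and 157 for CpG-B against CpG-C. The highest other split gave 0, 0, 1, 1 and 1 genes, so 1 of 10 splits reached the real count in each. For CpG-A against CpG-C, where the real count was 0, all 10 splits reached it and the highest other gave 1.

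The lower identity genes with CpG-B were weighed against 3 technical explanations. A lower share of the sorted cell type in the CpG-B libraries, diluting its transcripts alike, would lower the members by 1 common factor, but 9 of 38 had a 95% interval wholly above the list's median of -1.89 against CpG-C. That excludes dilution as the only cause and leaves open a part of it, since natural killer genes were higher in the same libraries and the sort gate is not described. The scaling of the values does not account for the falls, with 16 under upper quartile scaling against 17, nor do the libraries numbered 1, which had the lowest mean correlation within their groups, with 20 falling without them. A response of the cells to CpG-B could remain, and beyond the comparison of treatment groups no biological explanation was tested.

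The libraries numbered 1 had the lowest mean correlation within their groups. CpG-B replicate 1 stood apart little, with a mean correlation of 0.837 and a weight of 0.866 against 0.842 and 0.906 for CpG-B replicate 2. For this pattern lower depth stays open: the library numbered 1 had the lowest estimated depth in all 4 groups, from 22800000 fragments in control replicate 1 to 24800000 in CpG-B replicate 1, but the estimates are rough, and with CpG-B the range over resampled genes, 24300000 to 25900000, overlaps that of replicate 2, 24900000 to 26800000. It had the fewest genes above 0 with CpG-A and the most in the other 3 of 4 groups, which low-level reads would raise, so this count does not decide. Low-level reads spread over genes the cells do not use are a candidate explanation: the library numbered 1 had the most olfactory receptor genes above 0 in all 4 groups, and the excess lay below 1 FPKM (101, 55 and 5 genes with CpG-A, 155, 33 and 11 with CpG-B, 112, 20 and 11 with CpG-C, 227, 60 and 12 in control), with 8 to 16 genes at 1 FPKM or more in any library. The highest olfactory receptor value was not low, from 173 to 349 FPKM (Olfr1318) in the libraries numbered 1 and from 53.4 to 189 FPKM in the others, and such reads do not account for it. No biological explanation was tested, and the origin of the low-level reads is not known.

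Nemf had very high values, from 2532 to 28092 FPKM. The span the table gives for Nemf, chromosome 12, 69159293 to 69361494, is wider than its annotation, 69310522 to 69357165, and holds 2 annotated 7SL genes, Rn7s1 and Rn7s2. Reads of 7SL RNA counted within the span of the gene are a candidate explanation for the high Nemf values. No biological explanation was tested.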
